A study of Homo sapiens with 12 samples.

How the data were processed

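THP-1 cells, wild type or with the S80A form of NFKB1, were treated with PMA at 25 ng/ml for 72 hr, rested for 4 days and treated with LPS at 10 ng/ml for 3 hr or left untreated, per the labels' protocols. Per the labels' protocols, poly(A) RNA was made into stranded TruSeq libraries and sequenced on a NextSeq 500 as single-end reads of 75 bases to a target of 20 M reads. The submitters' processing notes name FastQC, HISAT, StringTie, Cuffdiff, HTSeq and DESeq2 and the build GRCh38, with no versions and no order, and the annotation and the strand setting of the counting are not given in the sources used here. The labels do not say how the edited cells were made or whether they are a single clone.

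The authors deposited 2 tables, 1 per genotype, each with the authors' log2 fold change of 3 hr over 0 hr, the authors' p-value and adjusted p-value, and a signal per library for all 12 libraries. The signal values deposited by the authors were read counts divided by 1 size factor per library, as the values themselves show. Every value in a library was a whole multiple of the library's smallest value above 0 (100% of values to within 0.01 reads), which gave size factors of 0.834 to 1.29 and the whole reads. Values of genes in both tables were identical. The tables hold only genes with an authors' adjusted p-value under 0.01 and an absolute log2 fold change over 1, 2335 in the wild-type and 2508 in the S80A table, and the ratio of adjusted to raw p-values implied 17486 tested genes in each, of which 3741 and 4034 were under 0.01. Genes outside both tables were not analysed here, so the counts of differences describe genes listed as responding to LPS, not the transcriptome. The positions in the tables are windows of 500 bases on chromosomes 1 to 10 that do not match the genes and were not used. Positions come from GENCODE release 29 on GRCh38, in which 2925 of the 3281 identifiers matched a gene name, and 162 of the 172 genes named by the rule or called for the difference had a single place. Present symbols of IRG1 and CCRN4L come from RefSeq synonyms. Genes with near-identical copies (CCL3L3, CCL4, CCL4L1) and genes with an antisense partner are uncertain, since the counting could divide or share their reads.

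Comparisons, tests, alternatives, gene lists and the rule for named genes were fixed before the data were examined. The rule took NFKB1 first, the 10 largest increases and decreases of each genotype among genes with at least the median expression of its table, the 10 smallest p-values in each direction for the difference between genotypes, up to 4 members of each list by wild-type response and 2 by difference, and the 5 largest changes per direction among genes listed in 1 table. The value of 1 gene that the rule takes is not reported here, and it is included in all counts. CXCR4, FOSL2, IL12B, LTA, MAP3K8, NFKB2 and PLAU, and in the closing section MX1, GBP2, GBP3, CDC20 and AURKA, fall outside it and were named after their values were seen. For the LPS response of each genotype the main result was the authors' calls, since the tables hold only called genes. The difference of the LPS response was tested with the limma interaction term on log2(scaled reads + 1) over the 1562 genes in both tables, in a fit of all 4 groups with 1 spread per gene. The genotype difference before and after LPS was tested with limma on the 6 libraries of that time, over all 3281 genes. Adjusted p-values are from the Benjamini-Hochberg method with a threshold of 0.05. Fold changes on the log2(value + 1) scale understate changes of genes with few reads. The floor is 3 reads over a group. Groups with 1 to 3 reads get a ratio of reads per size factor with an exact 95% counting interval.

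The 17 gene lists were compared in 2 ways. Fisher's exact test, two-sided, set rises against falls among the members in a table against all other genes of that table. For the 10 lists with at least 5 members in both tables, the median difference was ranked among 10000 random lists matched on expression quintile and direction, with a two-sided permutation p. Permutation p-values of lists treat the members as independent genes. They do not measure the spread between libraries and can be too small where members move together. Bootstrap intervals used 10000 draws of genes. R 4.3.3 with limma 3.58.1, edgeR 4.0.16 and DESeq2 1.42.0, and Python 3.11.15 with matplotlib 3.10.9 were used. On simulated counts for the 1562 genes of the interaction test, 11% of differences of 1 log2 and 77% of differences of 2 log2 were recovered, with 6 false calls among 94. Differences of about 1 log2 or less were therefore mostly beyond the power of 3 libraries per group, and some of 2 log2 were missed as well. The list test, on simulated data, found the 1 shifted list and called 0 of the others. Every member of that list was shifted alike, by more than the median difference of any list in the real data. The simulated genes were independent, so this check does not cover smaller shifts, members in both directions or members that move together.

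The replicate numbers in the labels paired the libraries within a genotype. Deviations from the group means of same-numbered libraries correlated at 0.343, 0.207 and 0.153 in wild-type and 0.299, 0.286 and 0.196 in S80A cells, all over 0.1. Between genotypes they did so at 0 hr (0.188, 0.245 and 0.259) and not at 3 hr (0.153, 0.196 and 0.064). The alternatives chosen beforehand were a threshold of 0.01, a minimum change, a filter at the 25th percentile of expression, a pseudocount of 0.1, the replicate number as a block, centring, a regression line in place of equality, the list mean, a rescaled median and leaving out each library. Alternatives added after the data were seen were the limma retest of the listed genes, edgeR's quasi-likelihood test and DESeq2 on the recovered reads, a limma trend, all genes of either table, the authors' fold changes, the floor, 1 spread from all groups, a block across genotypes, and leaving out both S80A libraries numbered 1. With the authors' size factors, edgeR called 74 of the 1562 genes for the interaction, and 58 of the 72 limma calls.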

Results

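RNA-seq was used to measure the transcriptional response to lipopolysaccharide (LPS), a bacterial outer membrane component sensed through TLR4, in THP-1 cells, a human monocytic leukaemia line that takes on macrophage features after treatment with a phorbol ester (PMA). The cells carried either wild-type NFKB1 or an NFKB1 gene edited to the S80A form, in which 1 serine of the NF-κB subunit p50 is replaced by alanine and can no longer be phosphorylated. The question was how much of LPS-induced transcription depends on this serine. The 12 libraries fell into 4 groups of 3, namely wild-type and S80A cells before LPS (0 hr) and after 3 hr with LPS at 10 ng/ml. Expression is given as read counts per gene divided by 1 size factor per library, called scaled reads. The 3281 genes covered were those that the authors listed as changed by LPS in wild-type cells (2335 genes), in S80A cells (2508 genes) or in both. Reads on these genes ranged from 1924562 in wild-type replicate 1 at 0 hr to 5789918 in S80A replicate 1 at 3 hr. These totals leave out all other genes and are not the depth of the libraries, for which the labels state a target of 20 M reads. Counting intervals and floors cover counting error only. The labels do not say that the replicates were separate cultures, so the p-values measure only the spread between these samples, which may be technical. Genotype also coincides with the edited cell line itself, so a difference between genotypes may include differences between lines.

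The LPS treatment separated the libraries along the first principal component, which held 71.1% of the variance, and the genotype separated them along the second, which held 17.6%. Within groups, Spearman correlations across genes, which are not independent replicates, ranged from 0.958 to 0.994. S80A replicate 1 lay nearer the wild-type libraries than S80A replicates 2 and 3 at both times, with second-component scores of 16.7 at 0 hr and 16.9 at 3 hr against 32.7 to 46.7 for the other S80A libraries. No replicate pair agreed within sampling noise, since chi-square per gene between pairs of a group ranged from 9.53 to 198.6.

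**Figure D1:**
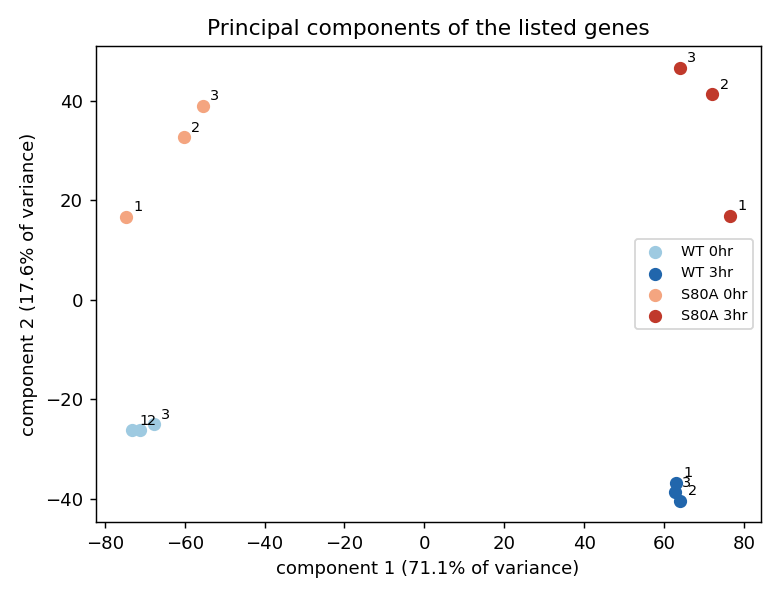
First and second principal components of log2(scaled reads + 1) over the 3281 listed genes, with 1 point per library numbered by replicate and coloured by group. The 0 hr libraries lie below -55 and the 3 hr libraries above 62 on the first component, and S80A replicate 1 lies nearer the wild-type libraries than S80A replicates 2 and 3 on the second.

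NFKB1, which encodes the p105 precursor of p50 and is itself an NF-κB target, was induced alike in both genotypes. It rose from 875 ± 100.4 to 23290 ± 713 scaled reads in wild-type cells and from 917 ± 151 to 23200 ± 4621 in S80A cells (SD, n = 3). The LPS response of NFKB1 differed by -0.08 ± 0.28 log2 (SE) between S80A and wild-type cells, with a limma adjusted p of 0.932. The gene lies on chromosome 4 from 102501329 to 102617302 on the plus strand of GRCh38. The codon of serine 80 in the transcripts that encode 968 residues lies at 102537939 to 102537941, in exon 5 of 24. A point edit leaves the read count of its gene unmarked, so the expression of NFKB1 gives no check of the genotype labels.

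Among genes at or above the median expression, the 10 largest increases in wild-type cells were those of IRG1, CCL4L1, CCL4, CCL8, IL6, TNIP3, IDO1, CCL3L3, RP11-701P16.5 and PTX3. IRG1 (present symbol ACOD1), which encodes the itaconate-producing enzyme of activated macrophages, had 1 read over the 3 libraries at 0 hr and 37914 at 3 hr, a ratio of 50180 with a 95% counting interval of 9005 to 1982000. IL6, a pyrogenic cytokine, went from 1 read to 4234, a ratio of 5603 with a counting interval of 1005 to 221400. TNIP3, an inhibitor of NF-κB signalling, had no reads at 0 hr and was at least 1404-fold higher at 3 hr against a floor of 3 reads over the group. The chemokine genes CCL4 and CCL8 rose from 23.4 ± 14.2 to 31250 ± 3343 and from 1.36 ± 0.911 to 6888 ± 1611 scaled reads (SD, n = 3). TNF, the first of the classical LPS-induced cytokines, rose from 67.0 ± 21.7 to 15400 ± 1200. IDO1, which degrades tryptophan, rose from 1.36 ± 0.916 to 2089 ± 467, and PTX3, a soluble pattern recognition protein, from 36.3 ± 10.1 to 15470 ± 4462. CCL4L1 and CCL3L3 had log2 fold changes of 11.02 and 9.13 in the authors' deposited table, and both are near-identical copies of other chemokine genes, so the counting could have divided their reads between copies. RP11-701P16.5 had no reads at 0 hr and was at least 661-fold higher at 3 hr. Among the largest decreases, MERTK, a receptor for the uptake of apoptotic cells, fell from 899 ± 101 to 77.0 ± 10.2, and CD180, a TLR-like surface protein, fell to 88.0 ± 28.65. ADORA3, an adenosine receptor, fell from 567 ± 183 to 38.6 ± 17.6, and the endocytic adaptor gene DAB2 fell from 4944 ± 1182 to 444 ± 133. TMEM86A, MTUS1, DLX3, USP2, EEPD1 and LRRC25 fell with log2 fold changes between -4.09 and -3.02 in the authors' deposited table. In all, 1441 genes rose and 894 fell in wild-type cells at an adjusted p under 0.01 and an absolute log2 fold change over 1 in the authors' deposited table. A limma retest of the listed genes, added after the data were seen, on log2(scaled reads + 1) called 1441 of the rising and 894 of the falling genes. The genes had been selected for this change in the same libraries, so the retest is no separate support.

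In S80A cells 7 of the 10 largest increases (IRG1, CCL4L1, CCL4, CCL8, TNIP3, IDO1 and PTX3) and 3 of the 10 largest decreases (DLX3, USP2 and LRRC25) were those of wild-type cells. IRG1 went from 1 read over the 3 libraries to 16244, a ratio of 20320 with a counting interval of 3646 to 802600. IDO1 had no reads at 0 hr and was at least 2279-fold higher at 3 hr, and TNIP3 was at least 1612-fold higher. CCL4 rose from 31.4 ± 5.00 to 36910 ± 3749 scaled reads and CCL8 from 1.03 ± 1.79 to 2249 ± 1334 (SD, n = 3). The neutrophil-attracting chemokine genes CXCL2 and CXCL3 rose to 4949 ± 682 and 4153 ± 665, and IL1A to 1924 ± 607. PTX3 rose from 17.3 ± 8.98 to 9876 ± 2674. The largest decreases included DLX3, a homeobox gene, which fell from 1128 ± 217.5 to 46.4 ± 24.2, and USP2, which encodes a deubiquitinase and fell from 1286 ± 321 to 79.9 ± 26.5. LYL1, a basic helix-loop-helix transcription factor gene, fell from 509 ± 54.5 to 43.3 ± 9.53. SNX18, ARHGEF3, LRRC25, C16orf54, PRR5L, SOX12 and PKDCC fell with log2 fold changes between -3.72 and -3.04 in the authors' deposited table. In S80A cells 1516 genes rose and 992 fell in the authors' deposited table, and the limma retest, with the same limit, called 1515 and 992 of them.

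The lists fixed beforehand for inflammatory genes rose together in both genotypes, in the authors' deposited table. Of 25 NF-κB subunits and feedback regulators, 24 rose in wild-type cells and 24 in S80A cells, among them TRAF1 (52.7 ± 8.26 to 20970 ± 1887 in wild-type cells, SD, n = 3) and TNFAIP3, the ubiquitin-editing inhibitor A20 (388 ± 168 to 31020 ± 2191). Of 25 inflammatory cytokines and growth factors, 21 rose in each genotype. IL1B reached 70030 ± 31050 in wild-type and 174300 ± 32900 in S80A cells. At 0 hr IL1B was at 90.93, 12.06 and 33.07 scaled reads in the wild-type and 152.4, 1802 and 4669 in the S80A libraries. Its response differed by -3.6 log2, S80A minus wild type (limma adjusted p = 0.2, range 0.00766 to 0.374 over 22 alternatives). IL23A reached 10180 ± 2439 in wild-type and 1339 ± 1225 in S80A cells. Of 28 chemokines, 17 rose in wild-type and 16 in S80A cells. Of 44 interferons and interferon-stimulated genes, 37 rose in wild-type and 38 in S80A cells, with IFIT2 reaching 45140 ± 7193 and 34260 ± 18060, and IFNB1 259 ± 107 and 208.5 ± 36.0. Of 27 immediate early transcription factors, 23 rose in wild-type cells, and 20 rose and 1 fell in S80A cells, with NR4A3 reaching 3472 ± 372 and 3039 ± 2117. Of 33 adhesion, matrix, prostanoid and coagulation genes, 21 rose in wild-type and 19 in S80A cells, among them PTGS2, the inducible cyclooxygenase (25.9 ± 4.36 to 4954 ± 2289 in wild-type cells), and VCAM1. Of 24 anti-inflammatory and signal-limiting genes, 16 rose and 1 fell in wild-type cells, and 15 rose and 3 fell in S80A cells, with SOCS3 reaching 7574 ± 1157 and 12170 ± 2669. Against all other listed genes, Fisher's exact test of rises against falls gave Benjamini-Hochberg adjusted p-values from 4.76e-07 to 0.012 for these 7 lists in wild-type cells. The same test gave 1.98e-07 to 0.00146 for the first 6 lists in S80A cells and 0.112 for the anti-inflammatory list, a contrast between genotypes that was not tested.

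The other lists did not pass that test in either genotype. Of 27 pattern recognition and inflammasome genes, 11 rose in each genotype, including IRAK2 (59.2 ± 14.6 to 4191 ± 360.4 scaled reads in wild-type cells, SD, n = 3), while 4 fell in wild-type and 3 in S80A cells. Of 27 antigen presentation and costimulation genes, 8 rose in wild-type and 6 in S80A cells, among them CD80, CD83 (398 ± 53.8 to 14270 ± 885 in wild-type cells) and CD40, with adjusted p-values of 0.0661 and 0.165. Of 24 glucose uptake and glycolysis genes, 4 rose in wild-type cells by symbol, namely SLC2A6, SLC2A3, HIF1A and PFKFB3, and 3 in S80A cells. These counts and the test leave out a further member, ACOD1, because members were matched by symbol. ACOD1 was listed as IRG1 and rose in both genotypes, with authors' log2 fold changes of 12.61 in wild-type and 11.37 in S80A cells. Of 23 unfolded protein and oxidative stress genes, 10 rose and 2 fell in wild-type cells, and 11 rose and 1 fell in S80A cells, with SOD2 rising from 1001 ± 204 to 95270 ± 1357 in wild-type cells and GCLC, which makes glutathione, falling. Of 29 cholesterol synthesis and efflux genes, 2 rose and 1 fell in wild-type cells and 5 rose in S80A cells, with INSIG1 and LSS rising in both. Of 31 macrophage surface and lysosome genes, 3 fell in wild-type cells and 1, MERTK, in S80A cells. Of 31 cell cycle genes, 2 rose and 1, PLK1, fell in wild-type cells, and 2 rose and 4 fell in S80A cells. Of 12 undifferentiated myeloid precursor genes, CD34 rose and CEBPE and GFI1 fell in both genotypes. Among 20 markers of other cell types CD79B alone was listed, falling in both genotypes, and among 24 signs of RNA quality 1, NEAT1, rose in wild-type and 2 in S80A cells. Apart from ACOD1, a member that is not listed did not pass the authors' thresholds, was not tested by them or may stand under another symbol. The tables do not tell these apart.

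The LPS responses of the 2 genotypes overlapped in 1562 genes, of which 1045 rose in both, 509 fell in both and 8 went in opposite directions. Independent lists of these sizes among the 17486 genes that the authors' adjusted p-values imply would share 125 rising and 50.7 falling genes. Over the 1562 shared genes, log2 fold changes of the 2 genotypes correlated with a Pearson r of 0.938 and a Spearman rho of 0.914, across genes, which are not independent replicates. These genes were selected for a change over 1 log2 in both genotypes, which raises the correlation, and over all 3281 listed genes the Pearson r was 0.868. NR5A2, a nuclear receptor gene, PLK2, a stress-responsive kinase gene, LGR4, FZD4, TPPP and LOC100505501 rose in wild-type and fell in S80A cells, and CXCR4, a chemokine receptor gene, and PIK3C2B did the reverse, in the authors' deposited table. PLK2 went from 67.6 ± 11.7 to 298 ± 77.9 scaled reads in wild-type cells and from 2742 ± 1379 to 490 ± 358 in S80A cells (SD, n = 3). PIK3C2B, a lipid kinase gene, went from 237 ± 46.4 to 67.5 ± 25.1 in wild-type cells and from 218 ± 81.8 to 825 ± 166 in S80A cells. All 8 passed the limma test of the difference between genotypes, with adjusted p-values from 0.00099 to 0.0139. They had been selected for changes over 1 log2 in opposite directions in the same libraries, so this test is no separate support.

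The size of the shared response was close between genotypes. Among the 1051 shared genes that rose in wild-type cells, the median absolute log2 change was 2.48 in wild-type and 2.59 in S80A cells, and the median of the paired differences was 0.05, with a 95% bootstrap interval over genes from -0.0002 to 0.0902. Among the 511 that fell, the medians were 1.64 and 1.62, and the median difference was 0.04 (0.0017 to 0.0763). Both medians changed with single libraries left out. For rising genes the median was -0.0692 without S80A replicate 1 at 0 hr, -0.0347 without it at 3 hr, -0.00217 without wild-type replicate 1 at 3 hr and at most 0.148, without S80A replicate 3 at 3 hr. For falling genes it was -0.0103 and -0.0752 without S80A replicate 1 at 0 hr and at 3 hr, 0.0086 and 0.0809 without S80A replicates 2 and 3 at 0 hr, and 0.0639 and 0.0892 without them at 3 hr. It was 0.0143, 0.0802 and 0.0231 without wild-type replicates 1, 2 and 3 at 0 hr, and 0.055 without replicate 2 at 3 hr.

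Many genes were listed in 1 genotype alone, and most of these moved the same way in the other. Of 390 genes listed as rising in wild-type cells alone, 181 also rose in S80A cells by limma, and of 469 listed as rising in S80A cells alone, 249 also rose in wild-type cells. Of 383 and 477 genes listed as falling in wild-type and in S80A cells alone, 224 and 293 also fell in the other genotype. The LPS response itself differed between genotypes, by limma over all 3281 listed genes, for 91, 128, 45 and 82 of these genes, in the same order of lists (390, 469, 383 and 477 genes). All had passed the authors' thresholds in 1 genotype and not in the other, in the same libraries. That selection favours a difference, so these counts can be too large and the adjusted p-values too small. This holds most for the genes named next, chosen for the largest changes. VILL, a villin-like gene, rose from 133 ± 18.04 to 1448 ± 135 scaled reads in wild-type cells and was at 99.3 ± 14.7 and 157 ± 107 in S80A cells (SD, n = 3; difference -2.98 ± 0.51 log2, SE, adjusted p = 0.00493). TGFBR3, a TGF-β co-receptor gene, rose from 106 ± 39.3 to 812 ± 132 in wild-type cells and was at 141 ± 33.9 and 220.0 ± 104 in S80A cells (adjusted p = 0.012). SFRP1 and WT1 rose in S80A cells, to 1605 ± 940 from 84.4 ± 25.9 and to 1472 ± 572 from 166 ± 41.8, against 192 ± 32.4 and 293 ± 22.9 in wild-type cells at 3 hr (adjusted p = 0.00615 and 0.0053). NRROS fell from 2847 ± 591 to 493 ± 61.9 in S80A cells and was at 2034 ± 356 and 1351 ± 219 in wild-type cells (adjusted p = 0.00413). For IGFBP3, DDIT4L, HMOX1, TRIB1, SH2D3C, ID3 and FAM84B, each listed in 1 genotype alone, the difference had limma adjusted p-values from 0.0917 to 0.571. TRIB1 (0.0917) passed with the replicate number as a block (0.0193), by edgeR (0.0483), by DESeq2 (0.0126) and without S80A replicate 1 at 3 hr (0.00907), within a range of 0.00537 to 0.184 over 22 alternatives. IGFBP3 passed by DESeq2 (0.034) and without S80A replicate 1 at 0 hr (0.0184; range 0.0184 to 0.458), HMOX1 by DESeq2 (0.0431) and without S80A replicate 1 at 3 hr (0.049; range 0.0431 to 0.192), and FAM84B without wild-type replicate 1 at 3 hr (0.0365; range 0.0365 to 0.467).

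A small share of the shared genes passed the limma test of a different LPS response between genotypes, in both directions. That test recovered 11% of simulated differences of 1 log2, so smaller differences may be missed. At an unadjusted p under 0.05 there were 312 of the 1562 shared genes. The shared genes had to be listed in both genotypes, which leaves out responses listed in 1 genotype alone and favours agreement. Over all 3281 listed genes 464 passed the adjusted threshold. That set includes genes listed in 1 genotype alone, whose selection favours a difference. KCNA3, a voltage-gated potassium channel gene, rose from 85.6 ± 6.84 to 439.9 ± 62.2 scaled reads in wild-type cells and from 4.00 ± 0.922 to 1155 ± 293 in S80A cells (SD, n = 3). CCRN4L (present symbol NOCT), a circadian gene, rose from 242 ± 16.6 to 1267 ± 152 in wild-type and from 68.7 ± 2.72 to 3725 ± 690.0 in S80A cells. SELE, the endothelial adhesion molecule E-selectin, had no reads at 0 hr in either genotype and reached 7.86 ± 5.42 in wild-type and 352 ± 72.2 in S80A cells. PDGFB, a growth factor gene, reached 94.4 ± 35.8 in wild-type and 1304 ± 406 in S80A cells from 12.2 ± 4.62 and 14.9 ± 4.24. In the other direction, IL6 reached 1538 ± 188 in wild-type and 272 ± 69.2 in S80A cells, and CCR7, the lymph-node homing receptor, 546 ± 151.5 and 29.8 ± 9.43. SLAMF7, a leukocyte surface receptor gene, rose from 61.0 ± 16.5 to 4616 ± 1900 in wild-type cells and from 972 ± 421 to 2231 ± 473 in S80A cells. OLIG1 reached 1119 ± 275 in wild-type and 38.9 ± 20.0 in S80A cells.

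By the limma interaction test, 72 of the 1562 shared genes had a different LPS response at a Benjamini-Hochberg adjusted p under 0.05, 44 with a higher and 28 with a lower value in S80A cells. Of these genes 36 rose more and 18 rose less in S80A cells, 4 fell more and 6 fell less, and 8 went in opposite directions. The differences, S80A minus wild type, were 5.49 ± 0.33 log2 for KCNA3 (SE, adjusted p = 5.00e-06), 3.35 ± 0.26 for CCRN4L (4.06e-05), 2.52 ± 0.30 for ABTB2 (0.00099), 2.07 ± 0.31 for KCNN2 (0.00346) and 3.50 ± 0.56 for PDGFB (0.00616). They were -4.86 ± 0.60 for SLAMF7 (0.00114), -6.23 ± 0.80 for NR5A2 (0.00118), -4.68 ± 0.70 for PLK2 (0.00381) and -3.07 ± 0.51 for OLIG1 (0.00773). The lower values of SLAMF7, NR5A2 and PLK2 went with higher resting levels in S80A cells. NR5A2 was at 4.33, 0.804 and 1.61 scaled reads in wild-type and 111.5, 207.9 and 350.5 in S80A libraries at 0 hr. At 3 hr it was at 38.8, 37.4 and 21.4 in wild-type and 41.5, 12.7 and 44.4 in S80A libraries. The level of SLAMF7 after LPS passed only in some alternatives. Of the 72 genes, 56 differed between genotypes after LPS, 30 before LPS and 14 at both times, by limma over all listed genes. Resting levels of SELE and IL6 were at 0 to 1 read, and edgeR on recovered reads gave adjusted p-values of 1 and 0.891 for their interaction (2.11e-06 to 1 and 0.00375 to 0.891 over 22 alternatives each), while their levels after LPS differed by 5.46 ± 0.42 and -2.52 ± 0.26 log2 (adjusted p = 0.000756 and 0.00107). CCR7, with 3 reads at 0 hr in S80A cells, had an interaction adjusted p of 0.15 by edgeR and of 0.00866 by limma (0.00384 to 0.296 over 22 alternatives). The counts of higher and lower genes were 31 and 18 without wild-type replicate 1 at 0 hr and 26 and 20 without replicate 3 at 0 hr. They were 23 and 15 without wild-type replicate 2 and 23 and 14 without replicate 3 at 3 hr. Without S80A replicate 2 at 0 hr they were 28 and 15. Without S80A replicate 1 they were 57 and 65 at 0 hr and 66 and 61 at 3 hr.

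**Figure D2:**
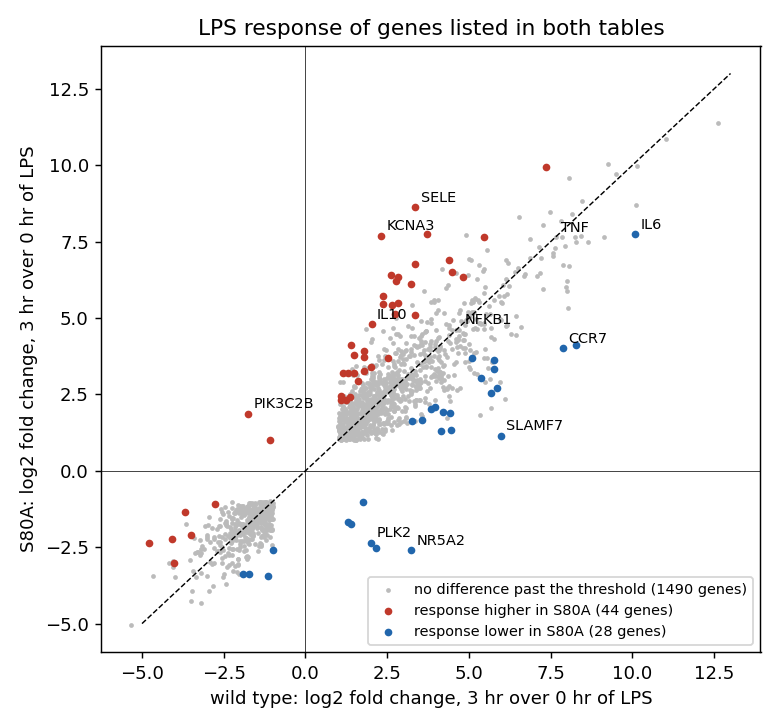
Log2 fold change from 0 hr to 3 hr of LPS in S80A cells against that in wild-type cells for the 1562 genes in both of the authors' deposited tables, with equal responses on the dashed line. The 44 genes with a higher response in S80A cells by limma are red and the 28 with a lower one blue, and NFKB1 and TNF lie near the line.

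**Figure D3:**
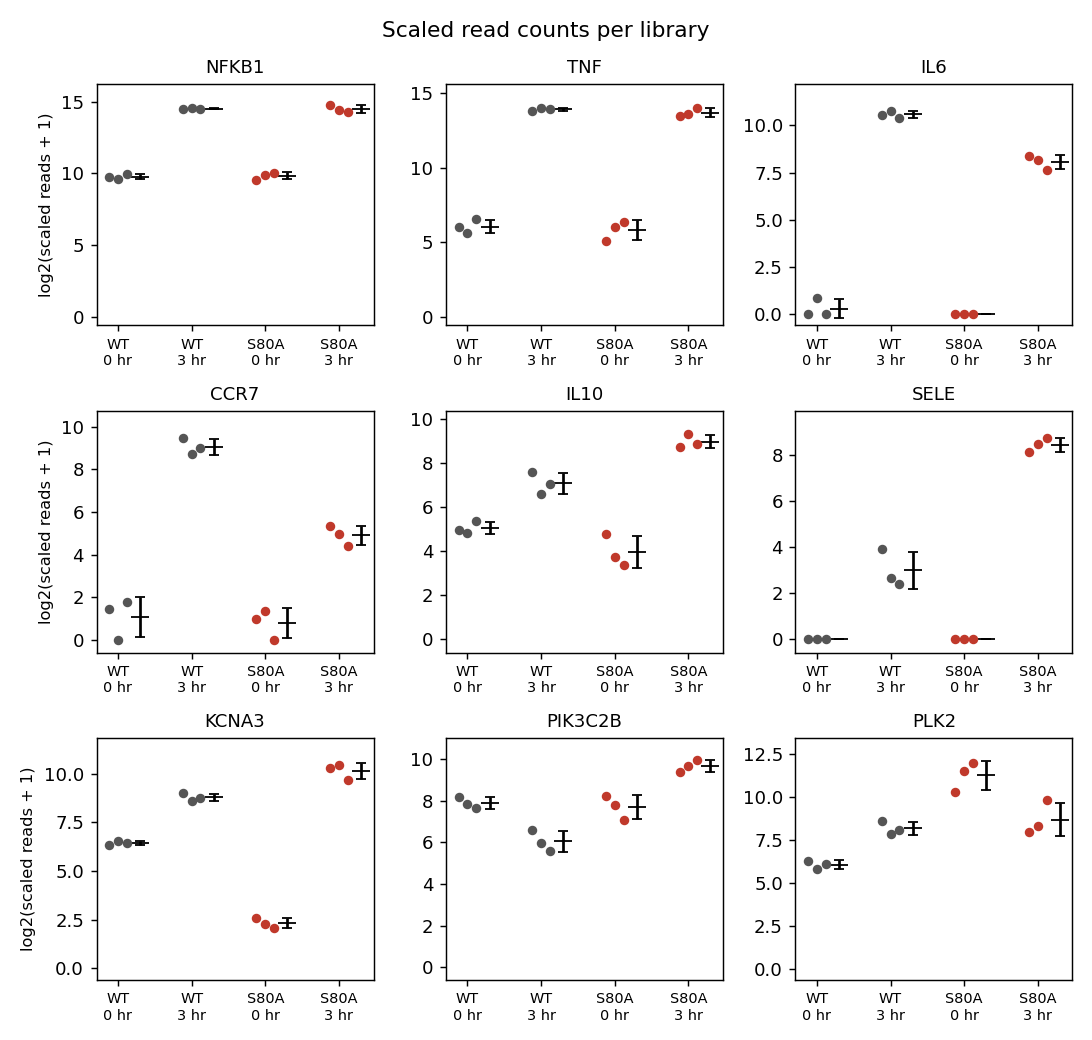
Scaled reads on a log2(value + 1) scale in each of the 12 libraries, with the mean and SD of each group of 3 beside the points, for 9 genes. NFKB1 and TNF reach similar levels in both genotypes, IL6 and CCR7 end lower in S80A cells and IL10, SELE, KCNA3 and PIK3C2B end higher, and PLK2 goes in opposite directions.

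Among the gene lists, the inflammatory cytokines and growth factors were induced less in S80A than in wild-type cells at the median. The median difference over the 20 members in both tables was -0.78 log2 against 0.04 in 10000 random lists matched on expression and direction (permutation adjusted p = 0.006), with 12 members lower and 8 higher. Over all shared genes 2 members passed, IL6 (lower) and CSF2 (higher, 16.0 ± 18.7 scaled reads in wild-type and 368 ± 221 in S80A cells after LPS, SD, n = 3), and 4 passed adjusted over the list alone, namely IL6, IL12B, LTA and CSF2. CSF2 had no reads at 0 hr in either genotype, and its interaction had adjusted p-values of 1 by edgeR and 0.325 by DESeq2 (0.00193 to 1 over 22 alternatives). IL12B and LTA had differences of -3.24 and -2.69 log2. TNF, the best known member, had a difference of 0.02 ± 0.47 log2 (SE). For the levels themselves, in a test chosen after the data were seen, the 22 members in either table had a median of 0.75 log2 above wild type before LPS (permutation adjusted p = 0.0403) and of 0.36 after LPS (0.945), where 9 members were higher and 5 lower. The call before LPS ended without wild-type replicate 1 (0.428, adjusted p = 0.391) or 2 (0.573, 0.158) and without S80A replicate 2 (0.651, 0.062) or 3 (0.403, 0.295). The mean of the list was -0.56, with a permutation adjusted p of 0.286, the median with a filter on low expression was -0.30 (0.299), and without S80A replicate 3 at 0 hr it was -0.51 (0.056), within a range of 0.002 to 0.299 over 25 alternatives. Members with few resting reads weigh on fitted differences, and the median was -1.001 with group means raised to the floor of 3 reads and -1.49 without such genes.

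The other 9 lists tested had permutation adjusted p-values from 0.285 to 0.912. NF-κB subunits and feedback regulators had a median difference of -0.12 log2, with 1 member past the threshold over all shared genes (MAP3K8, a kinase gene downstream of TLR4, -1.48) and 6 adjusted over the list alone, among them NFKB2 (-1.30) and NFKBIZ (1.68). Chemokines had a median of -0.25 and a mean of 0.16, with opposite signs, and 2 members passed over all shared genes, CXCL2 (2.65 ± 0.55 log2, SE) and CXCL6 (2.91 ± 0.72), against 3 adjusted over the list alone. Anti-inflammatory and signal-limiting genes had a median of -0.19, with 1 member past the threshold over all shared genes, IL10 (2.97 ± 0.52, adjusted p = 0.00866), and 5 adjusted over the list alone, including DUSP5 (-2.63) and ATF3 (-1.64). IL10, the main anti-inflammatory cytokine of macrophages, rose from 32.7 ± 6.80 to 139.9 ± 48.0 scaled reads in wild-type cells and from 16.2 ± 9.34 to 511 ± 108 in S80A cells (SD, n = 3). Adhesion, matrix, prostanoid and coagulation genes had a median of -0.37 and a mean of 0.07, also opposite in sign, with SELE and the urokinase gene PLAU (1.96) past the threshold over all shared genes and 2 adjusted over the list alone. Interferons and interferon-stimulated genes had a median of 0.10, with 0 of 36 members past the threshold by limma over all shared genes or over the list alone, 0 by edgeR and 2 at an unadjusted limma p under 0.05. With the replicate number as a block, USP18 of that list passed (-1.26 log2, adjusted p = 0.0498, range 0.0498 to 0.519 over 22 alternatives), as did DUSP5 (0.0201, range 0.00051 to 0.145) and the immediate early gene NR4A1 (0.0403, range 0.00855 to 0.228). GBP4 of the interferon list passed by DESeq2 (0.0144, range 0.0144 to 0.186) and without S80A replicate 1 at 0 hr (0.0308) or replicate 2 at 3 hr (0.0456), and DUSP5 and NR4A1 passed without S80A replicate 1 at 0 hr (0.00124 and 0.0109). The medians were -0.18 for immediate early transcription factors (1 member, FOSL2, over all shared genes and 1 adjusted over the list alone), 0.06 for pattern recognition genes (1 and 1, TLR2), 0.57 for antigen presentation and 0.04 for stress genes, both with 0 and 0 by limma, 0 by edgeR and 0 and 2 members at an unadjusted limma p under 0.05. TLR2, the receptor for bacterial lipoproteins, rose from 1971 ± 317 to 4262 ± 368 in wild-type and from 2263 ± 904 to 12730 ± 478 in S80A cells. Its difference of 1.44 ± 0.37 log2 (SE) had an adjusted p of 0.0485 that rose to 0.0571 with the replicate number as a block, and 11 of the 12 fits that left out 1 library took TLR2, and 10 took CXCL6, past 0.05 (up to 0.125 and 0.12), as did the fits without wild-type replicate 2 or 3 at 3 hr for CXCL2 (0.0564 and 0.0602) and the fit without wild-type replicate 2 at 3 hr for CSF2 (0.0556). The chemokine list passed without wild-type replicate 3 at 0 hr (median -0.73, adjusted p = 0.01).

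**Figure D4:**
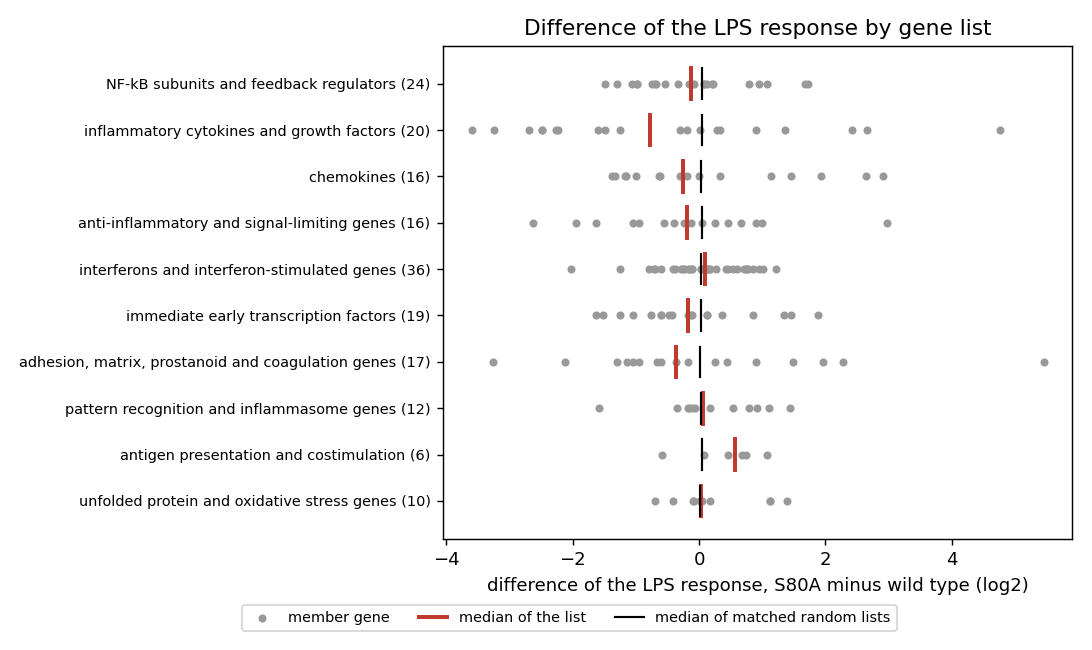
Difference of the LPS response between S80A and wild-type cells in log2 for each member (grey points) of the 10 gene lists with at least 5 members in both tables, with the number of members in parentheses. Red bars mark the medians of the lists and black bars those of matched random lists, and the cytokine list lies farthest below its random lists, at -0.78 against 0.04.

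Before LPS, many LPS-responsive genes already differed between genotypes. NR5A2, PLK2 and FZD4, a Wnt receptor gene, stood 6.11 ± 0.58, 5.18 ± 0.45 and 3.80 ± 0.31 log2 higher in S80A cells (SE, limma adjusted p = 0.00355, 0.00346 and 0.00328). SLAMF7 was 3.89 ± 0.43 log2 higher (adjusted p = 0.00458). KCNA3 stood at -4.13 ± 0.17, CCRN4L at -1.80 ± 0.11 and CXCR4 at -2.28 ± 0.17 log2 relative to wild type (adjusted p = 0.00181, 0.00216 and 0.00328). Over all 3281 genes, 660 were higher and 347 lower in S80A cells, so that 65.5% of the calls were higher. The median over the shared genes was shifted by 0.19 log2, and relative to that shift 473 genes were higher and 491 lower, or 49.1% higher. With 2 libraries left in a group the counts fell to 389 higher and 227 lower (without wild-type replicate 1), 342 and 187 (replicate 2), 328 and 169 (replicate 3) and 312 and 205 (without S80A replicate 2), and rose to 786 and 414 without S80A replicate 1.

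After LPS, the genotypes differed at more genes. SELE, CSF2 and PDGFB stood 5.46 ± 0.42, 4.76 ± 0.87 and 3.80 ± 0.39 log2 higher in S80A cells (SE, limma adjusted p = 0.000756, 0.00523 and 0.00116), and TLR2 was 1.58 ± 0.18 log2 higher (adjusted p = 0.00149). OLIG1 stood at -4.90 ± 0.38, CCR7 at -4.16 ± 0.32, LGR4 at -2.88 ± 0.37 and IL6 at -2.52 ± 0.26 log2 relative to wild type (adjusted p = 0.000756, 0.000756, 0.00185 and 0.00107). TNF and NFKB1 differed by -0.23 ± 0.22 and -0.02 ± 0.21 log2 (adjusted p = 0.421 and 0.936). Over all 3281 genes, 959 were higher and 582 lower, or 62.2% higher, and relative to the median shift of 0.19 log2 the numbers were 794 and 727, or 52.2% higher. Without wild-type replicate 2 or 3 at 3 hr, the number of lower genes fell to 383 and 363.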

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

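Chosen only after results were seen were the split of residuals, the tests of the level of gene lists before LPS, the tests of 1 scaling factor and of a difference already present before LPS, and the test of a batch shared by libraries numbered 1.

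A test of the difference itself set apart 72 genes whose LPS response differed between wild-type and S80A cells, 44 higher and 28 lower in S80A cells. In 7 of 100 drawn splits of the libraries as many genes passed, so this test did not exclude chance (real value 72, highest other 821). The split with 821 genes exchanged the genotypes at 3 hr alone, and all 6 other splits as large, this one included, kept the 3 wild-type libraries of a time together, which points to the genotype difference common to both times as a structure of the samples. With that difference left in place, 1 of 100 splits of the residuals, the real one, gave as many genes (real value 72, highest other 0). This second test was added because of the first outcome, so it does not settle whether chance is excluded. A single scaling factor per library is argued against by a median difference over shared genes of 0.0043 log2 (interval -0.0308 to 0.0372, smallest called difference 1.01). Different resting levels with equal final levels are argued against for the 56 of the 72 genes that differed after LPS. For the 16 genes that differed before LPS only, that explanation stays open. Too few reads stays open as a technical explanation, since 36 of the 72 genes, exactly at the bound of 0.5 set beforehand, had 20 scaled reads or more in all groups against 69.8% of shared genes, and edgeR called 22 of the other 36; an effect of the S80A edit or of the cell line may also contribute, and these coincide in this design.

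Among the genes with the smallest p-values in this test were the following differences in log2, S80A minus wild type. Higher were KCNA3 (5.49), CCRN4L (3.35), SELE (5.46), ABTB2 (2.52), PIK3C2B (3.81), LOC100506098 (3.78), IGSF22 (2.66), KCNN2 (2.07) and PDGFB (3.50). Lower were LOC100505501 (-4.56), TPPP (-2.98), SLAMF7 (-4.86), NR5A2 (-6.23), PLK2 (-4.68), LGR4 (-2.94), OLIG1 (-3.07), IL6 (-2.24), FZD4 (-3.20) and CCR7 (-3.87).

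S80A replicate 1 lay nearer the wild-type libraries at both times, by 37.7% of the distance between genotypes at 0 hr and 30.8% at 3 hr. Wild-type cells or RNA mixed into it are argued against as the whole cause, since genes high in wild type gave a mixed share of 15.2% and genes high in S80A 60.8% at 0 hr, a difference of -45.6 percentage points (interval -52.2 to -36.4), and -39.9 at 3 hr; S80A replicates 2 and 3, whose shares were negative, also had intervals that exclude 0 (14.7 and 22.2 at 0 hr, 15.0 and 23.9 at 3 hr), so these differences count only by their larger size, and a mixed share of up to 15.2% at 0 hr and 18% at 3 hr stays open. A batch shared by all libraries numbered 1 stays open, since its test covered the genotype axis alone. Along that axis wild-type replicate 1 was shifted toward wild type by -3.2% at 0 hr and -7.7% at 3 hr, that is, the other way. Same-numbered libraries of the 2 genotypes correlated at 0 hr (0.188, 0.245 and 0.259). In all 4 groups replicates 2 and 3 were the closest pair by chi-square per gene (9.53, 10.06, 36.96 and 59.76). The bound of that test was restated from size to direction after these values were seen, and read by size the ratio of -0.25 at 3 hr would not have met the bound of 0.2. A culture of S80A cells with another history may remain as an explanation, and none was tested.

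Before LPS, 660 genes were higher and 347 lower in S80A cells. Resting S80A cells partly resembling LPS-treated cells were tested only over genes listed in both genotypes. Genes that fell in both had a median of 0.232 log2 above wild type (interval 0.153 to 0.314) and genes that rose 0.229. Their difference of -0.002 log2 (interval -0.095 to 0.105) holds under any scaling and shows no resemblance across these genes. Genes already near their LPS level in resting S80A cells could miss the S80A threshold, so the test cannot decide for all responsive genes. A resemblance in part of the genes stays open, since the cytokine, immediate early, adhesion and anti-inflammatory lists stood 0.753, 0.658, 0.708 and 0.705 log2 higher (adjusted p from 0.0403 to 0.0483), and S80A replicates 2 and 3 lay toward the LPS side of the first principal component (-60.2 and -55.4 against -67.8 to -73.1 in wild-type cells) while replicate 1 did not (-74.7). Each of these 4 list calls ended with single libraries left out (for example 0.403, adjusted p = 0.295, for cytokines without S80A replicate 3 and 0.481, 0.375, for the anti-inflammatory list without wild-type replicate 1), and that of the immediate early list also with a pseudocount of 0.1 (0.0569), so they are weak evidence. A scaling shift of the S80A libraries also stays open, since rising and falling genes were shifted alike.

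For the comparisons of 3 against 3 libraries, 10 splits are too few for a share under 0.05. As many genes passed in 1 split each, the real one, for the LPS response in wild-type cells (2887, highest other 0), in S80A cells (2920, highest other 0), and for the genotype difference before LPS (1007, highest other 0) and after LPS (1541, highest other 0). For the LPS responses the listed genes had been selected by the real split, so its lead was built in and says nothing about chance.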

How the results depend on the processing

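Chosen only after the data were seen were the limma retest of the listed genes and the alternatives with edgeR, DESeq2, a limma trend, all genes of either table, the authors' fold changes, the floor, 1 spread from all groups, a block across genotypes and both S80A libraries numbered 1 left out. None of the results named for a gene or list that were past the threshold changed direction, while some that were not did, such as the chemokine and adhesion lists with the mean. Of the LPS responses 2120 values kept their side of the threshold and 8 lost it (ABCG1, CD163, CCNE2 and E2F7 in wild-type cells), of the differences 1655 kept it, 57 gained and 92 lost it, and of the levels 2474, 46 and 76. The limits are 3 libraries per group, tables of called genes alone and few resting reads.

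A threshold of 0.01 gave 14 higher and 10 lower responses in S80A cells, fewer by construction. A filter on low expression and the list mean left 0 lists past the threshold. For falling genes the sign of the global size reversed with the orthogonal slope, at -0.007904 (rising -8.253e-05), and with both S80A libraries numbered 1 left out, at -0.1071 (rising -0.1368), where 86 responses were higher and 114 lower. DESeq2 called 90 and 75, edgeR with TMM over the listed genes called 42 and 42, and limma over all listed genes called 236 and 228. Lower genes before LPS numbered 536 when rescaled and 528 with TMM, because the median shift was removed. For the others the cause was not tested. The replicate number as a block gave 55 higher and 38 lower responses and moved no count by over 1.5 times.

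With 1 library left out at a time, higher responses ranged from 23 to 66, lower ones from 14 to 65, lists past the threshold from 0 to 2, and the global size from -0.06925 to 0.1479 for rising and from -0.07517 to 0.08922 for falling genes, reversed at -0.01028 and -0.07517 without S80A replicate 1 at 0 hr and at 3 hr. Before LPS, higher genes ranged from 312 to 786 and lower ones from 169 to 414, and after LPS lower ones from 363 to 698. With 2 libraries left in a group fewer calls were open to the test, but the larger counts without S80A replicate 1 go with its place near the wild-type libraries.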

Other observations

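The tests of the level of gene lists were chosen only after the data were seen, and the genes MX1, GBP2, GBP3, CDC20 and AURKA after their values were seen, while the limma tests of single genes were fixed beforehand.

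Interferons and interferon-stimulated genes stood lower in S80A than in wild-type cells at the median at both times, with members in both directions. MX1, an antiviral GTPase gene, was at 1646 ± 1111 scaled reads in wild-type and 191 ± 127.5 in S80A cells before LPS and at 15370 ± 3578 and 2678 ± 1104 after LPS (SD, n = 3; limma adjusted p = 0.0286 and 0.00247). GBP5, a guanylate-binding protein gene, was at 58.9 ± 15.5 and 5.74 ± 4.52 before LPS and at 5194 ± 1875 and 536 ± 190 after LPS (adjusted p = 0.00891 and 0.00167). GBP2, GBP3 and GBP4 of the same list were higher in S80A cells before LPS, by 0.91, 0.99 and 2.19 log2 (adjusted p = 0.00895, 0.0142 and 0.0173), the last of which ended without wild-type replicate 1 (2.21, 0.0555) or 3 (1.92, 0.0571) or S80A replicate 2 (2.01, 0.0643). The median over the 39 listed members was -0.68 log2 before and -0.57 after LPS, S80A minus wild type, against 0.25 and 0.34 in matched random lists. The permutation adjusted p was 0.0012 at both times, from the smallest p that 10000 random lists can give. It treats the members as independent genes and does not measure the spread between libraries. Of the members 3 were higher and 5 lower before LPS, and 2 higher and 5 lower after LPS. With 1 library left out the median was -0.345 without wild-type replicate 2 and -0.43 without S80A replicate 3 before LPS, and -0.28 without S80A replicate 3 after LPS.

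The 6 cell cycle genes listed as changed by LPS were also lower in S80A cells at the median. CDC20, an activator of the anaphase-promoting complex, was at 6929 ± 978 scaled reads in wild-type and 1213 ± 452 in S80A cells before LPS and at 3398 ± 818 and 435 ± 338 after LPS (SD, n = 3; limma adjusted p = 0.00482 and 0.00342). PLK1 was at 1818 ± 173 and 338 ± 42.8 before LPS and at 855 ± 117 and 121 ± 70.0 after LPS (adjusted p = 0.00216 and 0.002). AURKA, a mitotic kinase gene, was at 1549 ± 193 and 499.8 ± 64.8 before and at 1117 ± 320 and 209 ± 101 after LPS (adjusted p = 0.0036 and 0.00277). The medians were -1.47 log2 before and -2.46 after LPS (permutation adjusted p = 0.0012 at both times), with 4 of 6 members lower before LPS and 4 lower and 1, E2F7, higher after LPS.

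Before LPS, 5 more of the 12 lists tested at each time passed that test. The medians, S80A minus wild type, were 0.75 log2 for inflammatory cytokines and growth factors (adjusted p = 0.0403), 0.66 for immediate early transcription factors (0.0483), 0.71 for adhesion, matrix, prostanoid and coagulation genes (0.0403), 0.70 for anti-inflammatory genes (0.0483) and -0.37 for unfolded protein and oxidative stress genes (0.0403). After LPS these 5 had adjusted p-values from 0.142 to 0.987. Each of these calls ended without some libraries of that time. The cytokine list had medians of 0.43, 0.57, 0.65 and 0.40 without wild-type replicate 1 or 2 or S80A replicate 2 or 3 (adjusted p up to 0.391), and the immediate early list 0.60, 0.62 and 0.58 without wild-type replicate 3 or S80A replicate 2 or 3 (up to 0.137), and 0.66 with a pseudocount of 0.1 (0.0569). The anti-inflammatory list had 0.48 and 0.74 without wild-type replicates 1 and 3 and 0.84, 0.52 and 0.51 without S80A replicates 1, 2 and 3 (up to 0.375). The adhesion list had 0.655 without S80A replicate 2 (0.062), and the stress list -0.185 and -0.194 without wild-type replicate 2 and S80A replicate 1 (0.106 and 0.083).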
